A study of Drosophila melanogaster with 8 samples.

How the data were processed

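The libraries come from 3' end sequencing (QuantSeq forward libraries, per the labels) of testes of bam mutant males, about 150 pairs of testes per library, in 4 groups of 2 libraries: control, cbc overexpression, PCF11 overexpression and both. Crosses were kept 3 days at 25 degrees and the progeny at 29 degrees, per the labels. The UAS transgenes sit on the second chromosome, and the controls carry none.

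Reads were aligned with Bowtie and handled with SAMtools to dm6/BDGP6, per the labels, which give no versions. The deposited tables hold raw read counts per poly(A) site, made by the authors with PolyA-miner, per the log of the run: windows of 30 bp around a supplied site list of 1098 positions, strand setting 0 (reads counted without strand), no molecular identifiers. The same settings list a gene minimum of 10, a site share minimum of 0.05, pa_p of 0.6, and pa_a and pa_m of 5. They also list a beta-binomial test and, as a separate setting, 100 iterations. The deposited result tables give each gene's mean proximal and distal fraction of reads, a score of distal against proximal usage, and a gene-level p-value with its adjusted p-value, per the file headers. The fractions and the authors' per-site test were not used here. How reads were trimmed and filtered is not given in the sources used here.

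The 3 count tables repeat the control columns, which held the same counts for shared sites, so all 8 libraries entered a joint set of 1082 sites in 529 entries (a gene and its transcript; 522 symbols). For each entry the reads at the most proximal site were set against those at all more distal sites. Tested entries had a mean of 10 or more reads per library and 5 or more reads at each side, summed over all libraries. These were 516, leaving out 13. Usage was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, with a term per library, a site term and a site-by-genotype term, all 8 libraries in 1 fit), and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The coefficient is the log2 odds ratio of proximal usage; its standard error was taken as the coefficient over the root of F and is approximate. Groups were compared with the control, with each other, and by an interaction term. Summed reads per gene were tested for 523 genes with TMM factors, so that changes are relative to the listed genes. Intervals of medians are 95% bootstrap intervals over genes. Per-library log odds for list tests and covariances used a pseudocount of 0.5. Library totals were not analysed here.

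Lists of 12 gene groups were fixed before the data were examined: cleavage and polyadenylation, RNA-binding and translation, splicing, chromatin and transcription, meiotic arrest and spermatocyte, cell cycle, kinases and signalling, ubiquitin and autophagy, vesicle and cytoskeleton, cyst and hub markers, sheath, muscle and fat markers, and spermatid markers; 9 had a tested member. Lists with 3 or more entries were tested with fry (whether a list moves one way on balance) and those with 5 or more with camera, at its preset and at an estimated correlation (limma 3.58.1), over 18 tests. The rule for naming genes was also fixed then: per comparison with the control, the 8 largest shifts in each direction among genes that passed with both libraries beyond both controls, the 4 largest rises and falls in summed reads, and list members that passed; for other comparisons, the 5 largest in each direction. Genes with 1 to 3 proximal reads in a group are given as a ratio of pooled shares with a 95% counting interval.

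The usage and count tests were checked on simulated data with 200 changed genes. Of shifts of log2 1, 2, 3 and 4 the edgeR usage test recovered 26.0%, 44.0%, 80.0% and 84.0% for cbc, 28%, 46.0%, 78.0% and 80.0% for PCF11, and 22.0%, 48.0%, 80.0% and 80.0% for both. The simulated shifts of log2 1 and 3 were all toward the proximal site, and those of 2 and 4 all toward the distal site. Recovery by size therefore cannot be told apart from recovery by direction. The count test recovered 82.0%, 74.0% and 76.0% of changes of log2 1, all of them falls. In the usage simulations edgeR called 118 of 516 entries in each comparison, against 39, 54 and 53 in the data. With more changed genes the adjustment of p-values is less strict, so recovery in the data may be lower.

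Coordinates are those of the deposited tables, on BDGP6. Of 17807 genes in the authors' gene list, 17017 matched a reference annotation of BDGP6 by symbol and 16955 of these (99.6%) had identical start and end, so that annotation placed the sites; 155 entries have a window that overlaps another gene, 120 of them on the opposite strand, and reads of such genes cannot be told apart. Alternatives were DESeq2 1.42.0, a block for the replicate number, a mean of 50 or more reads, no minimum, the most distal site against all others, only the 4 libraries compared, other scaling factors for summed reads, and each library left out. List tests without entries of 3 or fewer reads at 1 side in both groups were added after the values were seen. Data were handled with the package data.table (1.17.8) and with pandas 2.3.3, and plots made with matplotlib 3.10.9 in Python 3.11.15.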

Results

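Poly(A) sites were counted by 3' end sequencing in testes of Drosophila melanogaster males mutant for bam, a gene that germ cells need in order to leave the spermatogonial divisions. Cbc and PCF11 are the fly Clp1 and Pcf11 proteins, which belong to the cleavage factor that acts at the 3' end of nascent transcripts. The Gal4-UAS system overexpressed cbc, PCF11 or both in 3 genotypes, each with 2 libraries, beside 2 control libraries of bam mutants without a UAS transgene. Reads at the listed sites came to 258161 and 333675 in the controls, 287046 and 244017 with cbc, 251163 and 238162 with PCF11, and 296166 and 287828 with both. These totals cover the listed sites and are not the depth of the libraries, whose totals were not analysed here. The median gene had 248 to 328 reads per library. At 261 reads, a share of 25% in control library 1 has a 95% exact binomial interval of 19.8% to 30.4%. Reads carried no molecular identifiers, so such intervals cover counting error only. Site counts of duplicates differed by more than that. Their chi-square over its degrees of freedom was 13.4 in the controls, 6.02 with cbc, 6.53 with PCF11 and 10.1 with both. P-values measure the spread between these libraries, of about 150 pairs of testes each; the labels call them duplicates and do not state separate cultures.

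The tables list 1082 sites in 529 gene entries, of which 505 have 2 sites and 24 have 3. Proximal usage is the percentage of a gene's listed reads at the site nearest its start, given as mean ± SD of 2 libraries per group. Most proximal sites (518) lie in an annotated 3' UTR, 445 distal sites do, and 73 distal sites lie downstream of the annotated gene. The authors supplied the site list, whose name pairs bam with spermatocytes; how it was made is not given in the sources used here, and it is not independent evidence of a direction. Transcripts of cbc and Pcf11 are not among the listed genes, so their overexpression was not measurable here.

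Overexpression of cbc alone was compared with the controls to see whether poly(A) site use in bam mutant testes differed. The controls carry no UAS transgene, so a shift cannot be assigned to cbc rather than to presence of a transgene. Proximal usage rose for 29 genes and fell for 10 of 516 by edgeR. DESeq2 called 107 genes, 62 toward the proximal and 45 toward the distal site, and edgeR on only the 4 libraries compared called 24. In Rop, a Sec1/Munc18 protein of vesicle fusion, proximal usage rose from 1.95% ± 0.807 to 36.5% ± 2.99 (SD, n = 2 per group). It rose from 33.3% ± 7.80 to 80.9% ± 2.42 in CG12099 and from 28% ± 7.56 to 80.0% ± 2.77 in TH1, a subunit of the negative elongation factor. It fell from 64.8% ± 1.21 to 18.9% ± 0.303 in CG31523 and from 84.2% ± 1.53 to 34.3% ± 5.34 in JIL-1, a histone H3 kinase. All 39 called genes had both cbc libraries beyond both controls.

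By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the shifts had log2 odds ratios (± approximate SE) of 4.81 ± 0.65 for Rop (adjusted p = 0.00378), 3.10 ± 0.30 for CG12099 (adjusted p = 7.47e-04), 3.38 ± 0.54 for TH1 (adjusted p = 0.00743). By the same edgeR test they were -2.99 ± 0.28 for CG31523 (adjusted p = 7.47e-04) and -3.34 ± 0.74 for JIL-1 (adjusted p = 0.0281). Proximal usage also rose in CG1486, from 6.32% ± 1.95 to 65.6% ± 8.40 (edgeR adjusted p = 0.0207). So it did in Cdk5, a cyclin-dependent kinase, from 22.2% ± 8.25 to 76.3% ± 1.24 (edgeR adjusted p = 0.0238), and in IntS6, an Integrator subunit, from 8.08% ± 5.73 to 37.4% ± 4.06 (edgeR adjusted p = 0.0450). E(bx) is a subunit of the NURF chromatin remodeller. Its entry E(bx)-PA, meant wherever E(bx) is called, had 3 of 646 reads in the control libraries and 40 of 510 in the overexpression libraries. The share ratio was 16.9 with a 95% counting interval of 5.38 to 85.3. Another tested entry, E(bx)-PC, pointed the other way without passing, from 3.80% ± 0.639 to 1.11% ± 0.514 (edgeR adjusted p = 0.178). The gene sno had 2 of 1142 against 24 of 781 reads, ratio 17.5, 95% counting interval 4.36 to 153. Its usage shift had an edgeR adjusted p of 0.0238, but its reads at the proximal site, tested alone, did not pass (edgeR adjusted p = 0.192). Toward the distal site, usage of the proximal site fell in Dph1, a diphthamide synthesis enzyme, from 43.5% ± 0.553 to 4.29% ± 0.473 and in CG8026 from 31.6% ± 1.58 to 4.94% ± 4.96 (edgeR adjusted p = 0.0250 and 0.0250). It fell in CG2765 from 22.7% ± 11.4 to 3.28% ± 1.22 and in CG11030 from 26.1% ± 9.56 to 4.16% ± 1.31 (edgeR adjusted p = 0.0250 and 0.0238). It fell from 2.12% ± 0.359 to 0.364% ± 0.0582 in Usp7, a ubiquitin-specific protease, and from 94.8% ± 1.71 to 77.1% ± 1.18 in ewg, a transcription factor (edgeR adjusted p = 0.00378 and 0.0103). Windows of Cdk5 and CG8026 overlap another gene, for Cdk5 on the opposite strand, which counting ignored, and for CG8026 on the same strand. Reads of the overlapping genes cannot be told apart, and these values are uncertain.

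On BDGP6, with coordinates as in the deposited tables, the entry Rop-PA lies on chromosome 3L (proximal window 4136866 to 4136896, distal window 4136350 to 4136380), CG12099-PB on 3L (proximal window 1555482 to 1555512, distal window 1555360 to 1555390) and TH1-PA on X (proximal window 16389177 to 16389207, distal window 16388820 to 16388850). CG31523-PC lies on 3R (proximal window 4466466 to 4466496, distal window 4465420 to 4465450), JIL-1-PB on 3L (proximal window 11080244 to 11080274, distal window 11079473 to 11079503) and Usp7-PB on X (proximal window 12024019 to 12024049, distal window 12023543 to 12023573). All of these windows lie in annotated 3' UTRs.

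**Figure D1:**
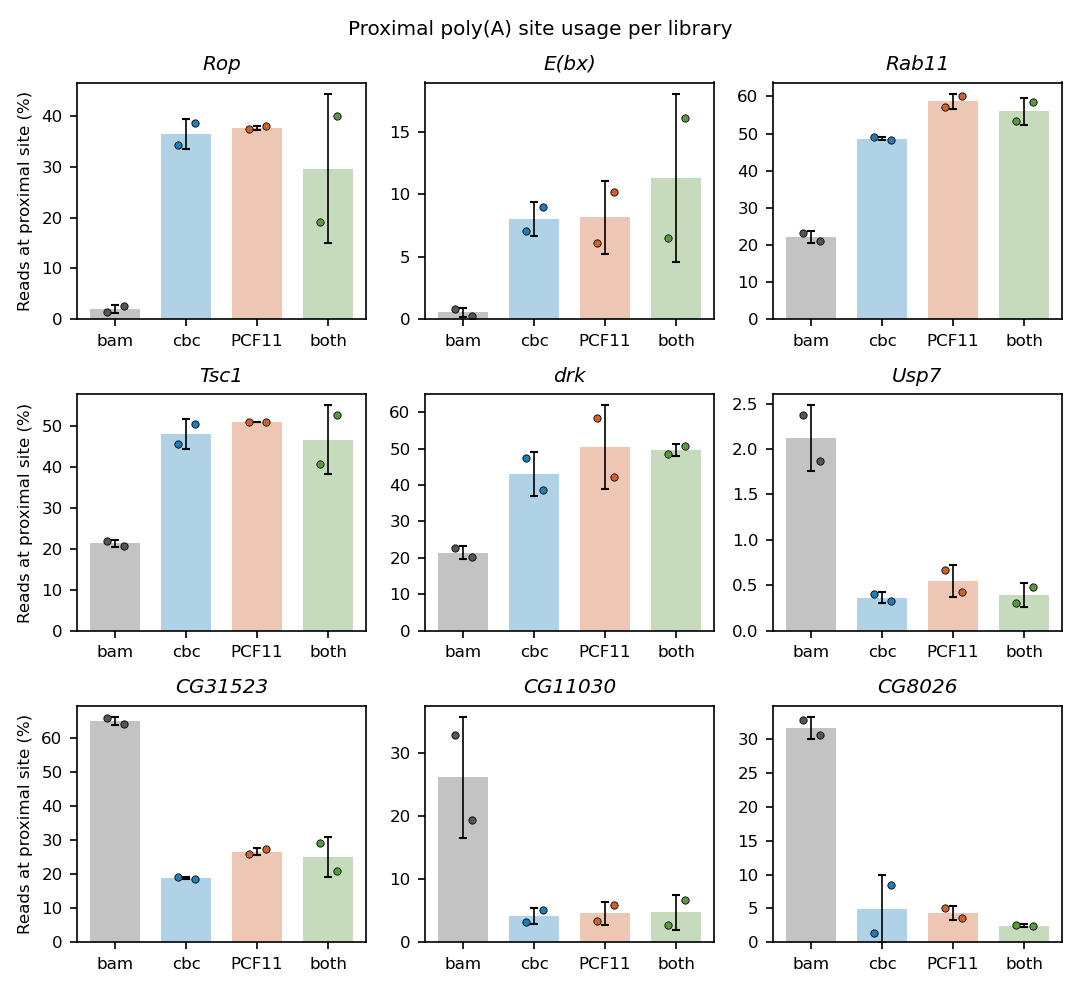
Percentage of reads at the proximal poly(A) site in the 9 genes that the naming rule picked in all 3 comparisons with the bam control; bars are means of 2 libraries, points are the libraries and error bars are SD, and each panel has its own axis from 0. In Rop the control libraries lie at 1.38% and 2.52%, and the 6 overexpression libraries between 19.2% and 40.1%.

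Among the fixed gene lists, the kinase and signalling list had 9 measured members, 3 of which shifted toward the proximal site with cbc. Adjusted over the list alone 4 passed, with Smurf added, which moved toward the distal site. Proximal usage of Smurf was 68.1% ± 14.9 in the controls and 39.5% ± 1.20 with cbc (edgeR adjusted p = 0.120 over all genes). Tsc1, which restrains TOR signalling, rose from 21.3% ± 0.790 to 48.0% ± 3.58 (edgeR adjusted p = 0.0250). The casein kinase dco rose from 2.96% ± 0.194 to 13.5% ± 4.31 (edgeR adjusted p = 0.0238), and drk, an adaptor of receptor tyrosine kinases, from 21.4% ± 1.78 to 43.0% ± 6.05 (edgeR adjusted p = 0.04998). In the vesicle and cytoskeleton list, 2 of 7 measured entries shifted toward the proximal site, also when adjusted over the list alone. They were the recycling endosome GTPase Rab11, from 22.1% ± 1.62 to 48.7% ± 0.535 (edgeR adjusted p = 0.00557), and the early endosome GTPase Rab5, from 15.0% ± 2.45 to 46.6% ± 3.85 (edgeR adjusted p = 0.0250). The proximal window of Rab5 on 2L (2360382 to 2360412) is intronic. In the chromatin and transcription list, 2 of 9 entries did, E(bx) and the co-Smad Med, and 2 when adjusted over the list alone. Med rose from 6.29% ± 2.52 to 19.4% ± 3.89 (adjusted p = 0.04998 by edgeR), and its window overlaps another gene. Of 6 ubiquitin and autophagy genes, Usp7 moved toward the distal site, the same number as adjusted over the list alone. None of 8 RNA-binding genes passed the edgeR test over all genes or adjusted over the list alone. Of 10 cell cycle genes none passed over all genes and 1 did when adjusted over the list alone. CycT, the measured member of the cleavage and polyadenylation list, had a log2 odds ratio of -0.74 ± 0.53 (adjusted p = 0.435 by edgeR), and simj, that of the meiotic arrest list, 0.31 ± 0.43 (adjusted p = 0.695). The splicing, sheath and spermatid lists had 0 measured members. Of the list genes called with cbc, Tsc1, dco, drk, Rab5, E(bx) and Med passed in none of the 4 fits without 1 library (highest edgeR adjusted p = 0.157, 0.172, 0.201, 0.178, 0.157 and 0.199). Rab11 and Usp7 were lost without cbc library 1 and without cbc library 2 (highest edgeR adjusted p = 0.0648 and 0.0530).

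The direction of each list on balance was tested with fry, adjusted over 18 list tests. The vesicle list moved toward the proximal site in all 3 genotypes (adjusted p = 0.0291 in each) and the kinase list with PCF11 (adjusted p = 0.0291). For kinases the adjusted p was 0.0940 with cbc and 0.159 with both. These 4 calls ended when entries with 3 or fewer reads at 1 side in both groups were left out, a step chosen after the values were seen (adjusted p = 0.0548 for each). That removed cnn-PI, an entry of the centrosome gene cnn, from the vesicle list with cbc and with PCF11, and the adjustment over all lists moved the other calls. The vesicle median was 0.77 with cbc and 1.23 with PCF11, or 0.75 and 1.05 without that entry, and 1.22 with both. Camera, which compares a list with the other genes, called no list: its lowest adjusted p was 0.452, and 0.794 with an estimated correlation. For the ubiquitin list with cbc, the median log2 odds ratio was 0.26 and the mean -0.07 and fry pointed to the distal site (adjusted p = 0.581). The cell cycle median with cbc was -0.18, or 0.05 without Cks30A (3 or fewer reads). The means were -0.60 and -0.31 and fry pointed to the distal site in both cases (adjusted p = 0.817 and 0.927). Camera placed chromatin genes with PCF11 and with both less toward the proximal site than the other genes. It did so too for cell cycle genes with PCF11 and for ubiquitin genes with cbc and with both. The medians of these lists were above 0, which is no conflict, because camera measures a list relative to the other genes. The adjusted p by camera was 0.999 in each.

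Summed reads of a gene, relative to the other listed genes, rose for 66 genes and fell for 55 of 523 with cbc by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CG2765 was at 9.73-fold (log2 3.28 ± 0.34, adjusted p = 4.50e-06) of the control, chb, the microtubule-binding CLASP protein, at 5.94-fold (log2 2.57, adjusted p = 7.93e-05) and CG5262 at 5.38-fold (log2 2.43, adjusted p = 8.31e-04). CG31697 was at 0.227-fold (log2 -2.14, adjusted p = 0.00632), CG2129 at 0.315-fold (log2 -1.67, adjusted p = 0.00382), strat at 0.338-fold (log2 -1.56, adjusted p = 3.75e-04) and gdl-ORF39 at 0.378-fold (log2 -1.40, adjusted p = 0.0348). Windows of CG31697 and gdl-ORF39 overlap another gene, so their reads are uncertain. Sec71, an Arf exchange factor, was at 5.78-fold (log2 2.53, adjusted p = 0.0137), and its controls differed from each other (70.7 ± 88.9 CPM with TMM factors). Its log2 change was 1.68 without control library 1 and 5.70 without control library 2. The count of 121 genes became 68 without cbc library 2. Of the 8 genes named here for their reads, CG2765, chb, CG5262 and strat passed without any 1 of the 4 libraries. Of the 8, 7 passed without control library 1, 6 without cbc library 1 and 5 without cbc library 2.

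Over all tested genes the median log2 odds ratio with cbc was 0.14 (95% interval over genes 0.04 to 0.26), and 0.08 without cbc library 2. The median proximal share was 18.4% ± 0.585 in the controls and 19.9% ± 1.02 with cbc (SD, n = 2), a difference of 1.44 points. An exact two-sided permutation test gave p = 0.333, the smallest that 2 against 2 libraries allow. Both cbc libraries lay above both controls for 148 genes and below for 107, where chance gives 33.3% of genes for the 2 places together. Without cbc library 1 or without cbc library 2 the usage test called 3 genes instead of 39, and without either control 25 (14 toward the proximal and 11 toward the distal site without control library 1), the lone library being assumed to vary like the other groups. Of the 22 genes named for usage, 2 passed without cbc library 1, 3 without cbc library 2, 9 without control library 1 and 11 without control library 2. CG12099 and CG31523 passed in every such fit. JIL-1 and Dph1 passed in none (highest edgeR adjusted p = 0.184 and 0.157).

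PCF11 alone was set against the same controls, with the same limit. Proximal usage rose for 47 genes and fell for 7 of 516 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). DESeq2 called 108 genes, 86 toward the proximal and 22 toward the distal site, and edgeR on only the 4 libraries compared called 25. Usage of the proximal site rose in Rop from 1.95% ± 0.807 to 37.7% ± 0.366, in Rab11 from 22.1% ± 1.62 to 58.7% ± 2.05, and in nonC, the kinase Smg1 of nonsense-mediated decay, from 41.8% ± 5.35 to 89.6% ± 4.32 (SD, n = 2 per group). In orb, the CPEB translation regulator of the germ line, it rose from 1.96% ± 2.46 to 16.7% ± 8.46, and in Cyclin A from 34.9% ± 1.68 to 57.1% ± 4.73. It fell in CG31523 from 64.8% ± 1.21 to 26.7% ± 0.994 and in pins, which orients mitotic spindles, from 22.0% ± 9.96 to 6.08% ± 1.03. All 54 called genes had both PCF11 libraries beyond both controls.

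The log2 odds ratios by edgeR were 4.89 ± 0.65 for Rop (adjusted p = 0.00526), 2.32 ± 0.26 for Rab11 (adjusted p = 0.00254), 3.63 ± 0.62 for nonC (adjusted p = 0.00892). By the same edgeR test they were 3.43 ± 0.89 for orb (adjusted p = 0.0420), -2.34 ± 0.27 for CG31523 (adjusted p = 0.00254) and -2.06 ± 0.52 for pins (adjusted p = 0.0376). Rab11-PB lies on 3R (proximal window 21115816 to 21115846, distal window 21116120 to 21116150), both in the 3' UTR, and nonC-PA on X (proximal window 6837877 to 6837907, distal window 6838115 to 6838145), the distal window downstream of the annotated gene. CG12099 rose from 33.3% ± 7.80 to 82.0% ± 0.0104 and CG1486 from 6.32% ± 1.95 to 50.5% ± 3.16 (edgeR adjusted p = 0.00116 and 0.0280). The gene retm rose from 1.98% ± 0.434 to 16.1% ± 6.31 and CG15484, whose window overlaps another gene, from 5.92% ± 3.27 to 51.2% ± 2.68 (edgeR adjusted p = 0.0222 and 0.0323). E(bx)-PA had 3 of 646 against 39 of 475 reads, ratio 17.7, 95% counting interval 5.62 to 89.4. E(bx)-PC stood at 3.80% ± 0.639 in the controls and 3.70% ± 1.99 with PCF11 (edgeR adjusted p = 0.954). Proximal usage fell in CG8026 from 31.6% ± 1.58 to 4.31% ± 1.04, in CG11030 from 26.1% ± 9.56 to 4.60% ± 1.79 and in Usp7 from 2.12% ± 0.359 to 0.547% ± 0.179 (edgeR adjusted p = 0.0192, 0.0190 and 0.00643). It fell in ewg from 94.8% ± 1.71 to 85.6% ± 4.07 and in Idh3b, an isocitrate dehydrogenase subunit, from 16.7% ± 1.44 to 8.35% ± 1.14 (edgeR adjusted p = 0.0423 and 0.0253). The window of CG8026 overlaps another gene.

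In the kinase list 3 of 9 genes shifted toward the proximal site with PCF11, and 3 when adjusted over the list alone. Tsc1 reached 50.9% ± 0.0522, dco 12.7% ± 0.453 and drk 50.4% ± 11.5, with edgeR adjusted p of 0.0128, 0.0189 and 0.0145. In the vesicle list Rab11 and Rab5 did, Rab5 reaching 38.9% ± 3.67 (adjusted p = 0.0423 by edgeR), 2 of 7 entries, and 3 when adjusted over the list alone. Cul3, a ubiquitin ligase scaffold, rose from 19.6% ± 3.08 to 38.7% ± 0.498 (adjusted p = 0.0128 by edgeR) while Usp7 fell, so that 1 of 6 ubiquitin genes moved each way, and 3 were called when adjusted over the list alone. E(bx) and Med, which reached 19.2% ± 1.91 (adjusted p = 0.0415), were 2 of 9 chromatin entries, and 2 when adjusted over the list alone. Cyclin A was the 1 of 10 cell cycle genes (adjusted p = 0.0128 by edgeR) and orb the 1 of 8 RNA-binding genes, each also 1 when adjusted over the list alone. CycT had a log2 odds ratio of -0.12 (adjusted p = 0.920) and simj 0.19 (adjusted p = 0.841). Of the list genes called with PCF11, Rab11 passed in every fit without 1 library, and dco and Rab5 in none (highest edgeR adjusted p = 0.0946 and 0.213). Tsc1, Cul3 and Cyclin A were lost without PCF11 library 1 and without PCF11 library 2 (highest 0.0790, 0.0787 and 0.0950). E(bx) and Med were lost without these and without control library 2 (highest 0.112 and 0.202), and orb without these and without control library 1 (highest 0.208). The call of drk was lost without PCF11 library 1 (0.104) and that of Usp7 without PCF11 library 2 (0.0567).

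Summed reads rose for 60 genes and fell for 52 with PCF11 by edgeR with Benjamini-Hochberg adjustment. CG2765 was at 6.07-fold (log2 2.60, adjusted p = 6.59e-05) of the control, the store-operated calcium channel Orai at 5.55-fold (log2 2.47, adjusted p = 7.59e-05), LRR at 5.43-fold (log2 2.44, adjusted p = 7.59e-05) and chb at 5.41-fold (log2 2.44, adjusted p = 2.06e-04). CG31697 was at 0.352-fold (log2 -1.51, adjusted p = 0.0410), gdl-ORF39 at 0.383-fold (log2 -1.39, adjusted p = 0.0410), the entry lola-PD of the BTB transcription factor lola at 0.428-fold (log2 -1.23, adjusted p = 0.00109) and CG17230 at 0.428-fold (log2 -1.22, adjusted p = 0.00438). Reads of chinmo, in the list of cyst and hub cell markers and also in the chromatin list, were at log2 -0.64 ± 0.16 (adjusted p = 0.0103 by edgeR), against -0.39 ± 0.16 with cbc (adjusted p = 0.0930). Those of zfh1, the other measured marker, were at -0.16 ± 0.20 (adjusted p = 0.60) and 0.25 ± 0.20 with cbc (adjusted p = 0.382). No usage call was made in these 2 markers with cbc or with PCF11, and 0 and 1 were called when adjusted over the list alone. Windows of CG31697 and gdl-ORF39 overlap another gene. The count of 112 genes became 46 without PCF11 library 1. Of the 8 genes named for their reads, CG2765, Orai, LRR, chb and lola passed in every fit without 1 library, and gdl-ORF39 in none (highest edgeR adjusted p = 0.205). Of the 8, 5 passed without PCF11 library 1, 6 without PCF11 library 2, 7 without control library 1 and 6 without control library 2.

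The median log2 odds ratio over genes was 0.36 (95% interval over genes 0.26 to 0.50). The median proximal share with PCF11 was 21.7% ± 1.16, 3.26 points above the controls (exact two-sided permutation p = 0.333). Both PCF11 libraries lay above both controls for 190 genes and below for 82, where chance gives 33.3% for the 2 places together. The usage test called 12 genes without PCF11 library 1 and 18 without PCF11 library 2, instead of 54. Of the 23 genes named for usage, 5 passed without PCF11 library 1, 6 without PCF11 library 2 and 14 without either control. CG1486, CG15484 and retm passed in none (highest edgeR adjusted p = 0.140, 0.162 and 0.140). CG12099, CG31523, Rab11 and Rop passed in every such fit, and the log2 odds ratio of orb became 6.31 without control library 2.

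With cbc and PCF11 together, proximal usage rose for 39 genes and fell for 14 of 516 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). DESeq2 called 113 genes, 81 toward the proximal and 32 toward the distal site, and edgeR on only the 4 libraries compared called 15. Usage of the proximal site rose in Rop from 1.95% ± 0.807 to 29.7% ± 14.8, in Rab11 from 22.1% ± 1.62 to 56.0% ± 3.58, in orb from 1.96% ± 2.46 to 21% ± 3.82, in nonC from 41.8% ± 5.35 to 90.9% ± 4.38 and in TH1 from 28% ± 7.56 to 75.4% ± 12.1 (SD, n = 2 per group). It fell in CG31523 from 64.8% ± 1.21 to 25.1% ± 5.85, in JIL-1 from 84.2% ± 1.53 to 30.6% ± 22.9 and in Usp7 from 2.12% ± 0.359 to 0.393% ± 0.128. The transcription factor zfh1, a marker of cyst stem cells, had 47 of 849 reads in the control libraries and 2 of 855 in the overexpression libraries, a share ratio of 0.0423 with a 95% counting interval of 0.00497 to 0.161. All 53 called genes had both combined libraries beyond both controls.

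By edgeR the log2 odds ratios were 4.31 ± 0.65 for Rop (adjusted p = 0.00979), 2.16 ± 0.26 for Rab11 (adjusted p = 0.00334), 3.90 ± 0.88 for orb (adjusted p = 0.0276). By the same edgeR test they were 3.84 ± 0.62 for nonC (adjusted p = 0.0110), 3.08 ± 0.55 for TH1 (adjusted p = 0.0135), -2.48 ± 0.27 for CG31523 (adjusted p = 0.00244). They were -3.80 ± 0.78 for JIL-1 (adjusted p = 0.0188) and -2.45 ± 0.32 for Usp7 (adjusted p = 0.00431), and zfh1 had adjusted p = 0.0458 by edgeR. CG15484 rose from 5.92% ± 3.27 to 49.2% ± 23.6 (adjusted p = 0.0380 by edgeR). CG32161 had 2 of 1470 against 26 of 583 reads, ratio 32.8, 95% counting interval 8.21 to 285. E(bx)-PA had 3 of 646 against 48 of 444 reads, ratio 23.3, 95% counting interval 7.50 to 117. E(bx)-PC again pointed the other way without passing, from 3.80% ± 0.639 to 1.38% ± 1.57 (edgeR adjusted p = 0.270). The gene sno had 2 of 1142 against 18 of 674 reads, ratio 15.2, 95% counting interval 3.65 to 136. Tested alone, reads at the proximal site did not pass for CG32161, sno and zfh1 (edgeR adjusted p = 0.275, 0.241 and 0.0631) and passed for E(bx) (0.0202). Proximal usage fell in CG8026 from 31.6% ± 1.58 to 2.48% ± 0.176 and in CG2765 from 22.7% ± 11.4 to 3.47% ± 2.01 (edgeR adjusted p = 0.0122 and 0.0224). It fell in CG11030 from 26.1% ± 9.56 to 4.77% ± 2.75 and in Nmda1 from 9.64% ± 5.80 to 1.75% ± 0.443 (edgeR adjusted p = 0.0241 and 0.0283). Windows of CG15484, CG32161, CG8026 and Nmda1 overlap another gene.

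In the kinase list Tsc1 reached 46.6% ± 8.35 and drk 49.5% ± 1.60 (0.0241 and 0.0183 as edgeR adjusted p), 2 of 9 genes, and 3 when adjusted over the list alone. Rab11 was the 1 of 7 vesicle entries, also 1 when adjusted over the list alone; Rab5 stood at 31.2% ± 17.5 (adjusted p = 0.147). Cul3 rose to 39.2% ± 0.738 (adjusted p = 0.0143 by edgeR) and Usp7 fell, 1 of 6 ubiquitin genes each way, and 3 were called when adjusted over the list alone. Cyclin A reached 54.5% ± 0.897 (adjusted p = 0.0241 by edgeR), 1 of 10 cell cycle genes and 1 when adjusted over the list alone. Of 8 RNA-binding genes orb shifted, and 2 did when adjusted over the list alone; E(bx) was the 1 of 9 chromatin entries, and 1 when adjusted over the list alone. Of the 2 cyst and hub markers zfh1 shifted toward the distal site, also 1 when adjusted over the list alone. Its summed reads were at log2 0.03 ± 0.20 (adjusted p = 0.924), and those of chinmo fell by 0.74 ± 0.16 on the log2 scale (adjusted p = 0.00292 by edgeR). CycT had a log2 odds ratio of -0.74 (adjusted p = 0.430) and simj 0.50 (adjusted p = 0.514). Reads of simj, the measured spermatocyte gene, were at log2 -0.56 (adjusted p = 0.0599), -0.50 with cbc (adjusted p = 0.114) and -0.54 with PCF11 (adjusted p = 0.0897). Of the list genes called with both, Rab11 and Usp7 passed in every fit without 1 library, and zfh1 and Cyclin A in none (highest edgeR adjusted p = 0.207 and 0.148). Tsc1 passed without combined library 1 alone and drk without control library 1 alone (highest 0.187 and 0.125). Cul3 and orb were lost without either combined library (highest 0.0838 and 0.111), and E(bx) without combined library 2 and without control library 2 (highest 0.0944).

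Summed reads rose for 94 genes and fell for 78 with both transgenes by edgeR with Benjamini-Hochberg adjustment. CG2765 was at 10.02-fold (log2 3.32, adjusted p = 5.00e-06) of the control, LRR at 6.92-fold (log2 2.79, adjusted p = 1.73e-05), Orai at 5.75-fold (log2 2.52, adjusted p = 4.67e-05) and CG5262 at 5.52-fold (log2 2.46, adjusted p = 6.32e-04). CG3309 was at 0.262-fold (log2 -1.93, adjusted p = 0.0264), gdl-ORF39 at 0.302-fold (log2 -1.73, adjusted p = 0.0105), CG31697 at 0.313-fold (log2 -1.68, adjusted p = 0.0188) and the nuclear receptor ftz-f1 at 0.337-fold (log2 -1.57, adjusted p = 0.00451). Windows of CG31697 and gdl-ORF39 overlap another gene. The count of 172 genes became 95 without combined library 2 and 114 with only the 4 libraries compared. Of the 8 genes named for their reads, CG2765, LRR, Orai and CG5262 passed in every fit without 1 library. Of the 8, 7 passed without combined library 1, 4 without combined library 2, all 8 without control library 1 and 6 without control library 2, where the log2 change of CG3309 was -1.10.

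The median log2 odds ratio over genes was 0.27 (95% interval over genes 0.08 to 0.37), and the median proximal share of 21% ± 0.248 lay 2.63 points above the controls (exact two-sided permutation p = 0.333). Both combined libraries lay above both controls for 169 genes and below for 110, where chance gives 33.3% for the 2 places together. The usage test called 7 genes without combined library 2 and 28 without combined library 1, instead of 53. Of the 21 genes named for usage, 4 passed without combined library 2 and 12 without each of the other 3 libraries. CG31523, Rab11, Rop and Usp7 passed in every such fit. Without control library 2 the log2 odds ratio became 6.77 for orb and 7.77 for CG32161, and CG32161 passed in none of the 4 fits without 1 library (highest edgeR adjusted p = 0.239).

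Setting the overexpression genotypes against each other asks whether PCF11 adds to cbc, and the reverse. No gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment for both transgenes against cbc (32 genes at an unadjusted p under 0.05, 12 by DESeq2 after adjustment), for both against PCF11 (18, and 1 by DESeq2) or for cbc against PCF11 (44, and 6 by DESeq2). Rop stood at 36.5%, 37.7% and 29.7% with cbc, PCF11 and both, CG12099 at 80.9%, 82.0% and 77.1%, and CG31523 at 18.9%, 26.7% and 25.1%. The median log2 odds ratio was 0.04 for both against cbc. It was -0.17 (95% interval over genes -0.21 to -0.13) for both against PCF11 and -0.26 (-0.35 to -0.19) for cbc against PCF11. These intervals leave out the spread between libraries. Median proximal shares per library were 19.13% and 20.58% with cbc, 20.86% and 22.50% with PCF11, and 21.22% and 20.87% with both. The PCF11 and combined libraries thus overlapped. The 95% interval of a single gene reached a median of 1.49 to either side on the log2 scale for both against cbc, so a count of 0 does not show that usage was equal.

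The interaction of the transgenes, the combined shift minus the sum of the single shifts, passed edgeR's test with Benjamini-Hochberg adjustment for 9 genes, 2 above and 7 below 0, and by DESeq2 for 55 genes, 12 above and 43 below 0. By edgeR it was -5.40 ± 0.86 for Rop (adjusted p = 0.0170) and -3.54 ± 0.41 for CG12099 (adjusted p = 0.00721), and 2.85 ± 0.38 for CG31523 (adjusted p = 0.0116), in each case a combined shift smaller in size than the sum. The median over genes was -0.27 (95% interval over genes -0.42 to -0.11). The test called 0 genes without cbc library 1, cbc library 2 or PCF11 library 1, 3 without PCF11 library 2, 2 without combined library 1, 4 without control library 1 and 6 without control library 2, and 12 without combined library 2.

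The 3 genotypes moved many genes alike. In all 3 comparisons 21 genes shifted toward the proximal site, among them Rop, Rab11, Tsc1, drk, TH1, nonC, E(bx), CG12099, the kinase Wnk, the transcription factor Deaf1 and the mismatch repair gene spel1, and 6 toward the distal site: CG11030, CG31523, CG8026, ewg, Idh3b and Usp7. Wnk, Deaf1 and spel1 were chosen here after their values were seen. Genes called toward the proximal site in both comparisons numbered 25 for cbc and PCF11, 23 for cbc and both, and 33 for PCF11 and both, where independent lists would share 2.64, 2.19 and 3.55. Toward the distal site they numbered 6, 9 and 7 against 0.136, 0.271 and 0.190, and none moved in opposite directions. All comparisons use the same 2 controls, so part of the excess may come from them. The controls were also the least alike of the duplicates. Spearman's rho of proximal shares across genes was 0.830 between the controls. It was 0.894, 0.909 and 0.886 within the cbc, PCF11 and combined groups. The edgeR fit estimates the spread from all groups together. In 50 simulations all 8 libraries, the controls too, were drawn from a share pooled over all libraries, and no gene was called in both comparisons. These simulations hold neither real effects nor the measured controls. That count therefore does not bound the part of the overlap that comes from the shared controls. The covariance of log2 odds ratios across genes was 2.14, 2.14 and 2.12, against simulated means of 0.429, 0.430 and 0.425. From per-library log odds it was 1.77, 1.72 and 1.72, of which the measured spread of the 2 controls accounts for 0.775, more than simulated. That leaves 0.990, 0.947 and 0.948 as the estimate of what the genotypes share apart from the control spread. Pearson's r across genes, which are not independent replicates, was 0.763, 0.735 and 0.781, against simulated means of 0.480, 0.492 and 0.491.

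**Figure D2:**
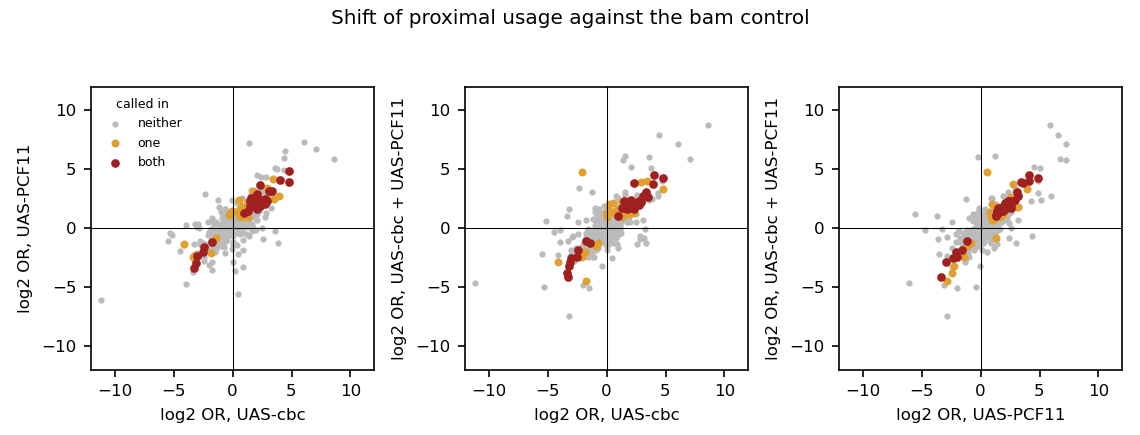
Log2 odds ratio of proximal usage against the bam control for each pair of overexpression genotypes, with 1 point per gene coloured by whether edgeR called it in neither, one or both comparisons. No gene was called in opposite directions, and Pearson's r lies between 0.735 and 0.781, part of which may come from the controls that the comparisons share.

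The authors' deposited table held 421 genes for cbc, 427 for PCF11 and 424 for both, of which 201, 222 and 233 had an adjusted p-value under 0.05. Of these, 119, 158 and 137 in the authors' deposited table were shortened and 82, 64 and 96 lengthened. Of the significant genes of the authors' deposited table, 37, 53 and 50 were also called by edgeR, all in the same direction, and 198, 220 and 232 had the same sign in the edgeR fit.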

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

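The tests of causes in this part, and the comparison of the controls with all 6 overexpression libraries, were chosen after the results were seen. The interaction test and its fits without 1 library were planned. The shift with both transgenes differed from the sum of the single shifts for 9 genes by edgeR's interaction term, and by DESeq2 for 55 genes, 12 above and 43 below 0. Proximal usage in control, cbc, PCF11 and combined libraries was 1.95%, 36.5%, 37.7% and 29.7% in Rop, with an interaction of -5.40 ± 0.86 (SE, adjusted p = 0.0170 by edgeR), and 33.3%, 80.9%, 82.0% and 77.1% in CG12099, with -3.54 ± 0.41 (SE, adjusted p = 0.00721 by edgeR). For sbb it was 5.50%, 28.4%, 23.6% and 18.8%, with -3.20 ± 0.48 (SE, adjusted p = 0.0170 by edgeR). For CG31855, whose window overlaps another gene, it was 40.5%, 83.6%, 77.2% and 75.3%, with -3.02 ± 0.59 (SE, adjusted p = 0.0464 by edgeR). For CG14207 it was 20.6%, 55.9%, 51.9% and 44.6%, with -2.71 ± 0.43 (SE, adjusted p = 0.0170 by edgeR). Above 0 were CG31523, at 64.8%, 18.9%, 26.7% and 25.1% with 2.85 ± 0.38 (SE, adjusted p = 0.0116 by edgeR), and Idh3b, at 16.7%, 5.60%, 8.35% and 8.87% with 1.85 ± 0.37 (SE, adjusted p = 0.0464 by edgeR). Of these 7 genes, none passed without cbc library 1, cbc library 2 or PCF11 library 1, 3 passed without PCF11 library 2, 2 without combined library 1, 6 without combined library 2, 4 without control library 1 and 5 without control library 2. Idh3b passed in none of these 8 fits (highest edgeR adjusted p = 0.193). In all 7 genes the single transgenes and the pair moved usage the same way from the control.

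Less than the sum of the single shifts was also the median over all genes, -0.27. A departure of 1 control library as the whole cause is argued against by the median without control library 1 (-0.25) and without control library 2 (-0.33), both below 0. A common offset between the 2 control libraries and all 6 overexpression libraries predicts a negative interaction for genes that rise, and the median of -0.27 cannot be told apart from one, because there is no second control group and no UAS control that lacks cbc and PCF11. A biological limit to the size of the shift stays open and was not tested.

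The second pattern is the shared direction of the 3 genotypes. Set against separate control libraries, so that no library was shared, the effects had a mean covariance of 0.973 (95% bootstrap interval over genes 0.666 to 1.26), which argues against the shared controls as its whole cause. Of 78 genes called between the 2 controls and the 6 overexpression libraries, 61.5% lay outside chromosome 2, which carries the transgenes. On it lay 38.5%, against 37.4% of tested genes (Fisher's exact p = 0.899). This argues against a difference that changes only genes on chromosome 2 as the whole cause. It does not speak to a difference on chromosome 2 that changes genes elsewhere. Of the 78 genes, 78.2% had no overlapping gene, against 70.5% of tested genes (Fisher's exact p = 0.137). This argues against reads of overlapping genes as the whole cause. Of the 28 splits of the 8 libraries into 2 and 6, 1 split, the real one, gave as many as 78 genes, and the highest other gave 2. That is the smallest share 28 splits allow, and every other split sets controls and overexpression libraries side by side in a group. The split was also chosen after the shared calls were seen. The libraries of a genotype are duplicates, so single libraries are not free to be exchanged between groups. The splits that kept the 2 cbc, 2 PCF11 or 2 combined libraries together gave 0 genes each. The rank of the real split therefore cannot exclude chance. Any other difference that sets the control libraries apart from all overexpression libraries, such as presence of a UAS transgene, stays open and was not tested.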

How the results depend on the processing

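No alternative reversed a named value: of 991 alternatives for 97 named values, 722 kept direction and call, 269 kept direction and lost the call. Genes called for usage against the control had both overexpression libraries beyond both controls. Leaving out 1 library could therefore not turn their shift, and the lack of reversals there was fixed in advance. Most lost calls came from fits without 1 library. Of 66 named usage values, 33 lost the call with only the 4 libraries compared. DESeq2, the read minimums and the other scaling factors kept nearly all. The setting without a shared control library was chosen after seeing the data. By DESeq2 the usage test called 107, 108 and 113 genes for cbc, PCF11 and both, which include every gene called by edgeR, 12, 1 and 6 for both against cbc, both against PCF11 and cbc against PCF11, and 55 for the interaction; the cause was not tested. Toward the proximal and the distal site these were 62 and 45 with cbc, 86 and 22 with PCF11, and 81 and 32 with both, against 29 and 10, 47 and 7, and 39 and 14 by edgeR. With only the 4 libraries compared, which leaves fewer samples to estimate the spread, usage calls were 24, 25 and 15, and summed reads with both transgenes called 114 genes. A replicate block, added although the replicate numbers do not pair the libraries (correlations of replicate differences between -0.0516 and 0.0684), gave 26, 41 and 42 usage calls and 5 for the interaction, against 115, 100 and 144 for summed reads. Without a shared control library, covariances were 1.002, 0.959 and 0.960 for cbc and PCF11, cbc and both, and PCF11 and both. Leaving out 1 library gave ranges of 3 to 25, 12 to 49 and 7 to 44 usage calls, 0 to 12 for the interaction, 68 to 144, 46 to 121 and 95 to 163 for summed reads, and 0.08 to 0.20, 0.28 to 0.45 and 0.20 to 0.27 for the median log2 odds ratio. The lone library was then assumed to vary like the other groups, and fewer samples remained. The comparisons between overexpression genotypes called 0 genes by edgeR without each library of the genotypes compared, under the block and under each read minimum. Read minimums and the most distal site gave 37 to 42, 54 to 55 and 53 to 55 usage calls. The smallest shifts called were 0.96, 0.94 and 0.98 on the log2 scale.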

Other observations

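The tests of reads at each site, of depth and of controls that share no library were chosen after the results were seen. Reads at each site were tested separately (edgeR with TMM, Benjamini-Hochberg adjustment). Of the genes called toward the proximal site, reads at the proximal site rose for 25 of 29 with cbc, 36 of 47 with PCF11 and 30 of 39 with both, and reads at the distal sites fell for 7, 22 and 16 and rose for 2, 1 and 3. In Rop with cbc the proximal site was at log2 4.59 (adjusted p = 2.07e-07) and the distal sites at -0.21 (adjusted p = 0.613); in CG12099 with cbc they were at 3.07 (adjusted p = 2.47e-10) and -0.00 (adjusted p = 0.998). Both rose in Rab11 with cbc, by 3.53 (adjusted p = 4.38e-08) and 1.80 (adjusted p = 3.69e-05). In Cyclin A and orb with PCF11 the distal sites fell, at -1.15 (adjusted p = 2.51e-04) and -1.31 (adjusted p = 4.19e-05), with proximal sites at 0.16 (adjusted p = 0.684) and 1.94 (adjusted p = 0.0289). Median log2 changes over the genes called toward the proximal site were 2.17, 1.49 and 1.62 at the proximal site and -0.31, -0.56 and -0.53 at the distal sites.

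Toward the distal site, the distal sites rose for 8 of 10 genes with cbc, 3 of 7 with PCF11 and 7 of 14 with both, and the proximal site fell for 5, 4 and 7. In CG31523 with cbc the proximal site was at log2 -1.02 (adjusted p = 0.00173) and the distal site at 1.98 (adjusted p = 1.93e-07). In CG11030 with cbc they were at -0.39 (adjusted p = 0.784) and 2.82 (adjusted p = 3.71e-08), and in JIL-1 at 0.68 (adjusted p = 0.133) and 4.0 (adjusted p = 6.31e-07). In Usp7 with cbc the proximal site fell by 2.61 (adjusted p = 0.00651) while the distal site was at -0.05 (adjusted p = 0.820). These genes were picked for their usage shift, so their site counts are not independent of it.

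A hypothesis stated before its test was that genes with more widely spaced sites shift more toward the proximal site. Spearman's rho across 516 genes, which are not independent replicates, between the mean shift of the 3 genotypes and the distance was -0.170 (two-sided permutation p = 0.00014, adjusted p = 0.00028 over 2 relations; Pearson's r = -0.110), the opposite direction. In 4 bins of 129 genes by distance, the median shift was 0.48 at 103 to 227 bp, 0.44 at 228 to 433 bp, 0.25 at 435 to 758 bp and -0.04 at 763 to 11957 bp. In these bins 17, 16, 15 and 9 genes were called toward the proximal site between the controls and all overexpression libraries, and 3, 4, 5 and 9 toward the distal site.

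A second hypothesis stated before its test was that genes that shift toward the proximal site gain reads. Over 12 combinations of 2 genotypes and 2 control libraries that share no library, Spearman's rho across genes between the shift and the read change was -0.0980 on average (range -0.133 to -0.0537; two-sided permutation p = 0.00229, adjusted p = 0.00229; mean Pearson's r = -0.108), again the opposite direction and small. The last hypothesis was that shifts come from genes of low depth. Among the 258 genes above the median depth the mean covariance between genotypes that share no control library was 0.973 (95% bootstrap interval 0.643 to 1.31), and below it 0.976 (0.527 to 1.47), which argues against low depth as the whole cause.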
